A study of Mus musculus with 8 samples.

How the data were processed

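RNA was measured in 8 libraries made from tdTomato-positive cells of the central amygdala of male mice, about 1000 sorted cells per library. The fluorescent reporter was switched on by Cre recombinase under the Prkcd promoter (PKCd libraries, n = 4) or the Sst promoter (SST libraries, n = 4). Tissue punches were dissociated with papain, cells were sorted by flow cytometry, and cDNA was amplified with a SMARTer kit, per the labels' protocols. Each library came from a different mouse, so the p-values measure the spread between mice together with the spread of sorting and amplification.

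Each deposited file gives, per transcript, the length, the effective length, an estimated count and a TPM value. Estimated counts were made by the authors with kallisto, and the file columns have that tool's names, per the file headers. The submitters' processing notes name kallisto 0.43.0, BWA 0.7.12 and the mm10 build, and the part played by BWA is not given in the sources used here. TPM values in the deposited files are scaled by the authors' tool to transcript length and to the same total in each library, so they keep no depth. A few abundant genes can lower the TPM of all others.

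Transcripts were joined to genes by RefSeq accession. Of 30404 targets, 30080 were named from the RefSeq gene table of GRCm38.p6, the patched form of the mm10 build, 147 from GENCODE names, and 177 kept only their accession. This gave 20692 genes. Estimated counts were summed per gene and rounded to whole numbers, and TPM was summed per gene. 70 target identifiers were repeated. Coordinates are 1-based and come from the same RefSeq table. Reads shared by near-identical genes were divided by the authors' tool, so values of such genes are uncertain.

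Library totals were 18242496, 10316149, 964361 and 1556245 estimated counts for PKCd replicates 1 to 4, and 14295789, 16009560, 1560934 and 2522749 for SST replicates 1 to 4. The mice of replicates 1 and 2 were 8 to 9 weeks old and those of replicates 3 and 4 were 18 to 20 weeks old. PKCd mice were 9 and 18 weeks old and SST mice 8 and 20 weeks old. Exact age within a class therefore cannot be told apart from population. Age class runs together with depth, and a sequencing run cannot be told apart from either. One read was worth 0.0548 CPM in the deepest library and 1.04 CPM in the shallowest. A count of 0 allows up to 3 counts, which is 0.165 CPM in the deepest library and 3.11 CPM in the shallowest. Intervals and such floors cover counting error only, since amplified reads are not independent molecules.

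The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM scaling, the default expression filter by population, and terms for age class and population. Adjusted p-values follow Benjamini and Hochberg with a threshold of 0.05. A log2 fold change is PKCd minus SST, and its SE was taken from the F statistic. The same model gave the older against younger comparison, and a model with 4 cells gave the comparison within each age class and the interaction. In simulated counts for the PKCd against SST comparison 200 genes were changed, and 10663 genes were left after the filter. Of these, 64 were changed 4-fold, 61 were changed 16-fold and 61 were changed 64-fold. The edgeR test recovered 0%, 29.5% and 80.3% of them, and it called 4 unchanged genes. DESeq2 recovered 15.6%, 68.9% and 93.4% and called 90 unchanged genes.

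27 gene lists were fixed before the data were examined, covering GABA and glutamate signalling, neuropeptides, ion channels, transcription factors, adhesion, the stress response and markers of other cell types. Lists were tested with camera (preset inter-gene correlation of 0.01, then an estimated one) and fry of limma 3.58.1, adjusted over the 26 lists with at least 3 tested members. Summed TPM of marker lists and the shares of GABA-A alpha subunits were compared by exact two-sided permutation tests in scipy 1.17.1, where 4 against 4 libraries cannot go below p = 0.0286. After adjustment over several lists or subunits a single such p cannot pass 0.05 alone. 3 further lists were added after the data were seen.

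The rule for named genes was also fixed before the data were examined. It takes Prkcd and Sst, then up to 10 genes in each direction with the largest fold change among those with adjusted p under 0.05, a mean of at least 10 CPM and no overlap between populations. It adds up to 6 list members past the threshold per list and the GABA-A alpha and gamma subunits, and it takes 5 genes in each direction for age class. Other genes named in the text were chosen after their values were seen. Some genes that the rule takes are not reported here.

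Alternatives were other scaling (RLE, upper quartile), no filter, a filter of 10 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), a length offset, no age term, the replicate number as a block, each age class alone, and each library left out. Thinning all libraries to the total of the shallowest was added after the data were seen.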

Results

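The profile of unchallenged neurons was compared between 2 populations of the mouse central amygdala, those that express protein kinase C delta (PKCd) and those that express somatostatin (SST). Each population had 4 libraries, and each library held about 1000 sorted cells of 1 mouse. Totals were 10316149 to 18242496 estimated counts in libraries of the 8 to 9 week mice and 964361 to 2522749 in those of 18 to 20 weeks. Libraries of the same population had a median Spearman correlation across genes of 0.603 (0.429 to 0.689), and libraries of different populations 0.525 (0.362 to 0.641); genes are not independent replicates.

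The first question was whether the genes that drive the reporter differed between the sorts. Prkcd (chromosome 14, 30595353 to 30626414, GRCm38), which encodes protein kinase C delta, stood at 177.7 ± 56.8 TPM in PKCd libraries and 10.5 ± 13.9 TPM in SST libraries (SD, n = 4 each). All 4 PKCd libraries, 106.5 to 225.7 TPM, lay above all 4 SST libraries, 0 to 30.2 TPM. The exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 allows, and 0.0571 after adjustment for both genes. In edgeR over all genes the log2 fold change was 5.36 ± 1.36 (SE), with an adjusted p of 0.219. Prkcd passed in 4 alternatives: edgeR with no filter (adjusted p 1.79e-07), DESeq2 (7.12e-05), limma on log2(TPM + 1) (0.0101) and edgeR after thinning to the shallowest library (0.0346), which was chosen after the data were seen; over all its alternatives the adjusted p was 1.79e-07 to 0.996. Sst (chromosome 16, 23889573 to 23891342), the precursor of somatostatin, stood at 237.8 ± 84.6 TPM in SST libraries and 60.2 ± 108.5 TPM in PKCd libraries (SD, n = 4 each). PKCd replicate 2 held 222.7 TPM of Sst, within the SST range of 116.3 to 296.2 TPM, and the other 3 PKCd libraries held 0.209 to 13.7 TPM. The exact permutation p for Sst was 0.0571, and its edgeR log2 fold change was -2.78 ± 1.63 (SE; adjusted p 0.845). Without PKCd replicate 2 it was -5.99 (adjusted p 0.366), and limma-voom on all libraries gave -5.18 (adjusted p 0.239).

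**Figure D1:**
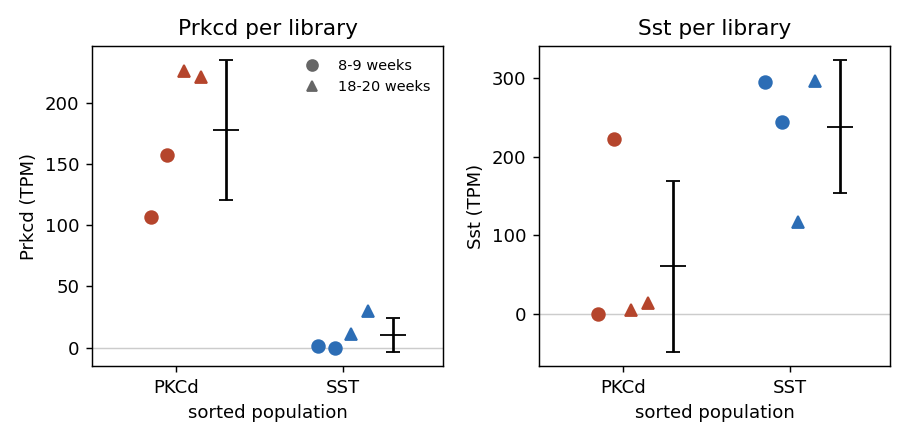
TPM of Prkcd and Sst in each library, by sorted population; circles are mice of 8 to 9 weeks, triangles of 18 to 20 weeks, and the black mark is the mean with its SD (n = 4). Prkcd lies at 106.5 TPM or above in PKCd libraries, while Sst in PKCd replicate 2, at 222.7 TPM, lies within the range of the SST libraries.

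The second question was which genes differed between the populations. Markers of microglia, the resident immune cells of the brain, were higher in PKCd libraries, and no gene was lower at the threshold. Of 11328 genes tested with edgeR, 32 were higher in PKCd libraries and 0 were lower at an adjusted p of 0.05, while 756 had an unadjusted p under 0.05; DESeq2 called 362 higher and 92 lower. 4 of the 32 genes belong to a list fixed beforehand, that of microglial markers. All 32 separated the 4 PKCd from the 4 SST libraries, as 771 of all tested genes did (6.81%, where chance gives 2.86%). All 32 had the same sign within both age classes, which follows from that separation and is no further evidence. Tested within 1 class, 0 of all genes passed at 8 to 9 weeks and 8 passed at 18 to 20 weeks. Leaving out 1 library gave 10 (without PKCd replicate 3 or SST replicate 3) to 52 genes (without SST replicate 1). All 32 then kept their sign, which their separation also requires. The count was also over 1.5 times lower without PKCd replicates 1, 2 and 4 (15, 21 and 17) and without SST replicate 4 (13).

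Slc2a5 (chromosome 4, 150119344 to 150144168), a fructose transporter, had 163.3 ± 58.1 TPM against 0.505 ± 0.475 TPM (SD, n = 4 each), a log2 fold change of 8.74 ± 1.05 (SE) and an adjusted p of 0.00728. Il10ra (chromosome 9, 45253837 to 45269149), a chain of the interleukin 10 receptor, had 51.0 ± 10.5 against 0.216 ± 0.296 TPM. Hvcn1, a proton channel, and Nckap1l, an actin regulator of blood cells, had 124.7 ± 47.4 and 100.8 ± 44.6 TPM in PKCd libraries and 0.703 ± 1.01 and 0.473 ± 0.436 TPM in SST libraries. Fgd2, Gmip and Arhgap45 had log2 fold changes of 7.77, 7.86 and 6.94. Havcr2, an immune checkpoint receptor, and Il4ra, a chain of the interleukin 4 receptor, had 3 reads and 1 read over the 4 SST libraries. Their pooled read rates were 1151 times (95% exact interval 393.7 to 5587) and 1369 times (245.2 to 54110) those of the SST libraries, with counting error only, and the ratios of mean CPM, which weight libraries equally, were 772.7 and 3655. They had adjusted p-values of 0.00728 and 0.0313 in edgeR. The Slc2a5 call held with each library left out. The Il4ra call ended in all 8 such fits (edgeR adjusted p 0.0517 to 0.148). Calls also ended in 6 fits for Nckap1l (all but SST replicates 1 and 2, 0.0796 to 0.139), in 5 for Il10ra (without PKCd replicates 1, 2 and 3 and SST replicates 2 and 4, 0.072 to 0.0862) and in 5 for Arhgap45 (without PKCd replicates 1, 2 and 3 and SST replicates 3 and 4, 0.0621 to 0.135). They ended in 4 for Hvcn1 (without PKCd replicates 1 and 3 and SST replicates 2 and 4, 0.052 to 0.0726), in 3 for Fgd2 (without PKCd replicate 3 and SST replicates 3 and 4, 0.0674 to 0.0894), in 3 for Gmip (without PKCd replicates 2 and 3 and SST replicate 3, 0.0734 to 0.085) and in 1 for Havcr2 (without PKCd replicate 3, 0.072).

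All 12 microglial markers were measured, 4 were higher over all genes (Tmem119, Cx3cr1, C1qa and Csf1r), and 12 of 12 were higher when adjusted over the list alone. Every one of the 12 was higher in all 4 PKCd than in all 4 SST libraries, with a median log2 fold change of 4.30. Tmem119 (chromosome 5, 113793729 to 113800396), a membrane protein of microglia, had 1265 ± 357.5 against 26.3 ± 18.8 TPM (SD, n = 4 each; log2 fold change 5.69 ± 0.61 SE, adjusted p 0.00484). Csf1r, the receptor that microglia need to survive, had 1610 ± 746.8 against 49.1 ± 42.3 TPM. Cx3cr1, the fractalkine receptor, had 559.6 ± 172.7 against 17.8 ± 12.5 TPM, and C1qa, a chain of complement C1q, had 3512 ± 888.5 against 156.4 ± 155.9 TPM. The Tmem119 call held with each library left out, while in edgeR the Csf1r call ended in 7 of the 8 fits (all but that without PKCd replicate 2, adjusted p 0.0581 to 0.215), that of C1qa in 6 (all but those without PKCd replicate 2 and SST replicate 1, 0.052 to 0.124) and that of Cx3cr1 in 2 (without SST replicates 2 and 3, 0.0532 and 0.096). The list passed camera at the preset correlation (adjusted p = 3.5e-30) and fry (adjusted p = 0.015). With an estimated correlation, 0.753 for this list against the preset 0.01, camera gave an adjusted p = 0.14. The preset p is therefore too small to be taken at face value. Camera at the preset also passed this list in a split balanced for population, PKCd replicates 1 and 2 with SST replicates 2 and 4 (adjusted p 3.7e-06). The preset camera call held with each library left out. The fry call ended without PKCd replicates 1, 3 and 4 and SST replicates 2 and 3 (adjusted p 0.0704 to 0.0837).

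**Figure D2:**
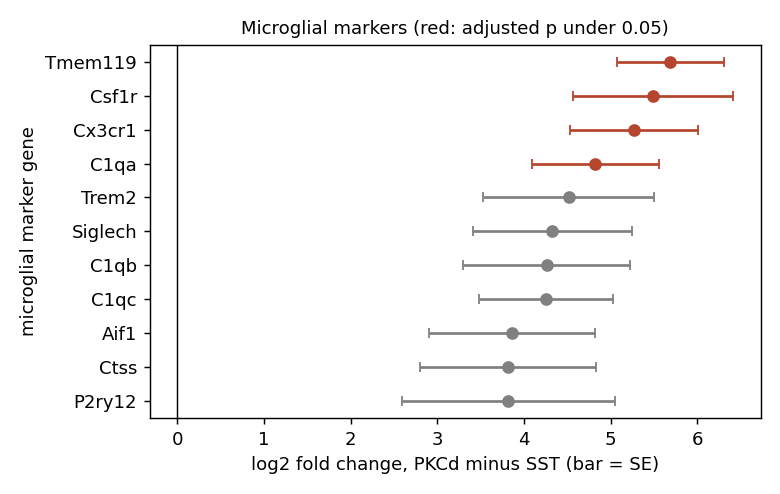
The log2 fold change (PKCd minus SST) of 11 microglial markers on the horizontal axis, with the SE as bars; red points have an adjusted p under 0.05. All 11 lie above 0, between 3.82 and 5.69.

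Summed TPM of the marker lists set the microglial difference beside those of other cells. Microglial markers summed to 39860 ± 10420 TPM in PKCd libraries and 2586 ± 2639 TPM in SST libraries (SD, n = 4 each), a ratio of 15.4, with exact permutation p = 0.0286 and 0.229 adjusted over 8 lists. Astrocyte markers summed to 1606 ± 849.1 against 2733 ± 462 TPM (exact p = 0.0571, adjusted 0.229). Oligodendrocyte markers, 21460 ± 7742 against 28510 ± 23450 TPM, and endothelial markers, 5287 ± 4693 against 3575 ± 4845 TPM, overlapped (exact p = 0.743 and 0.514). Mural cell and erythrocyte markers (exact p = 0.429), oligodendrocyte precursor markers (0.457), excitatory forebrain neuron markers (0.6) and other interneuron markers (0.429) overlapped as well. The sum of mural cell and erythrocyte markers joins genes that went opposite ways. Of its 8 tested members, 5 passed adjusted over the list alone and 0 over all genes. Acta2, Vtn and Rgs5 were lower in PKCd libraries (log2 fold change -3.56, -2.71 and -1.69). Hba-a1 and Hba-a2 were higher (4.80 and 6.26), but they are near-identical copies, so the division of reads between them is uncertain. Each of these 5 genes overlapped between the populations.

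**Figure D3:**
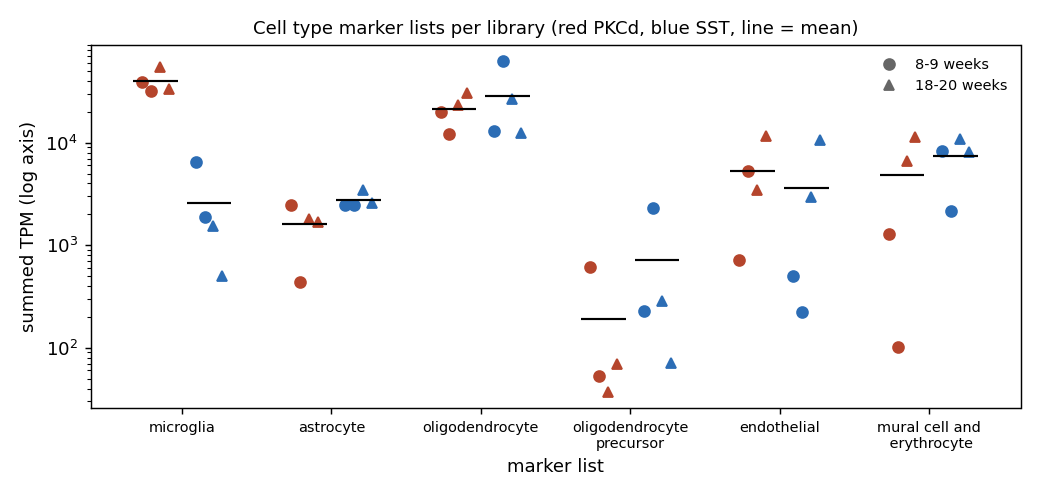
Summed TPM per library (log axis) for 6 marker lists; red is PKCd, blue is SST, circles are 8 to 9 weeks, triangles 18 to 20 weeks, and lines are means. Microglial sums are 31680 TPM or more in PKCd libraries and 6446 TPM or less in SST libraries.

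Genes of SST neurons were tested as a list: 4 of 12 members could be tested, 0 passed over all genes and Pdyn passed adjusted over the list alone. Sst, whose promoter defines the sort, is among the 4 tested, so the list is not independent of the sort. Its log2 fold change, -2.78, was the smallest in size of the 4. Pdyn, the precursor of dynorphin, had 43 ± 22.4 TPM in SST libraries and 0.275 ± 0.508 TPM in PKCd libraries (SD, n = 4 each; adjusted p 0.155 over all genes in edgeR). It had 3 reads over the 4 PKCd libraries, and its mean CPM in SST libraries was 166.4 times that in PKCd libraries. The ratio of pooled read rates, which is weighted to the deep libraries, was 686.6 (95% exact interval 234.6 to 3332, counting error only). The list had a median log2 fold change of -4.62 and passed fry (adjusted p = 0.015) and camera (0.00047); adjusted p = 0.14 with an estimated correlation. Its fry call ended without PKCd replicates 3 and 4 and SST replicates 2 and 3 (adjusted p 0.0669 to 0.198) and with no filter (0.0695). It passed camera with each library left out, but its median was then -2.31 to -5.77: -2.98, -2.31 and -2.75 without PKCd replicates 1, 3 and 4, and -2.87 and -2.31 without SST replicates 3 and 4. It was -2.40 with no filter and -2.48 with no age term. Prkcd passed adjusted over the PKCd neuron list alone, which the sort by its own promoter favours. The other tested members, Calcrl, Penk, Ezr and Cyp26b1, did not pass (log2 fold change -0.89, 0.41, 1.06 and 0.64). The PKCd neuron list did not pass camera (adjusted p = 0.176).

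GABA-A receptor subunits, which include the targets of benzodiazepines, had no member past the test. Of 19 subunits, 9 had enough reads to be tested and 0 passed over all genes or adjusted over the list alone. Gabra2, Gabra3, Gabra4, Gabra5 and Gabrg1 had log2 fold changes of -4.03 ± 1.90, -2.85 ± 3.32, -1.31 ± 1.96, -3.88 ± 2.28 and -1.32 ± 1.27 (SE), each with an adjusted p of 0.766 or more; Gabra4 was positive in 4 alternatives and Gabra3 in 1. Gabra6 and Gabrg3 had too few reads to be tested. The list median was -1.84; camera gave an adjusted p = 0.024, and adjusted p = 0.38 with an estimated correlation. The camera call ended without PKCd replicates 2 and 4 and SST replicates 3 and 4 (adjusted p 0.0542 to 0.344; medians -1.23, -1.08, -1.72 and -1.04) and with no filter (0.0839). As shares of alpha subunit TPM, Gabra2 was 14.3 ± 16.9% in PKCd and 32.2 ± 33.6% in SST libraries and Gabra4 was 34.8 ± 44.5% and 21.9 ± 23.5% (SD, n = 4 each). The exact permutation p was 0.429 or more for each alpha subunit (adjusted 0.96 or more). The libraries held from 3 to 1251 alpha subunit reads. Deep libraries of 1 population differed as well: Gabra3 was 1.08% in PKCd replicate 1 (950 reads) and 69.2% in PKCd replicate 2 (297 reads), and Gabra2 was 23.8% in SST replicate 1 (1251 reads) and 81.4% in SST replicate 2 (1244 reads).

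Cadherins and protocadherins had a median log2 fold change of -1.25 with 0 of 14 tested members past the threshold. Pcdh11x and Pcdh15 passed adjusted over the list alone. Both were highest in SST replicate 2 (18.3 and 36.7 TPM), which also had the highest oligodendrocyte precursor sum (2307 TPM). PKCd replicate 1, with a precursor sum of 610.8 TPM, had 0 and 1.26 TPM. Which cells gave the cadherin and glutamate receptor reads was not tested. The cadherin list passed fry (adjusted p = 0.015) and camera (0.002), with an adjusted p = 0.14 in camera with an estimated correlation. The camera call ended without PKCd replicate 2 (median -0.43, adjusted p 0.0791) and without SST replicate 2 (-1.23, 0.077), and the fry call without PKCd replicates 1 and 4 and SST replicates 1, 2 and 3 (0.0524 to 0.0839). Ionotropic glutamate receptors (median -1.24, 12 tested, 0 passed) passed fry at 0.0355 and camera at 0.0237; adjusted p = 0.263 with an estimated correlation. Their camera call ended without PKCd replicates 1, 2 and 4 and SST replicates 2 and 3 (adjusted p 0.114 to 0.269), and their fry call with each of the 8 libraries left out (0.0664 to 0.367), with no filter (0.0866) and with no age term (0.316). Metabotropic glutamate receptors (median -0.96, 4 tested, 0 passed) passed fry at 0.0276 and did not pass camera at 0.11; the fry call ended in 7 of the 8 fits with 1 library left out (all but SST replicate 1, adjusted p 0.0544 to 0.248). With the replicate number as a block none of the 5 lists that passed fry did so (adjusted p 0.0558 each). In all, 13 lists passed camera with its preset correlation and 0 with an estimated one. Beside those above, benzodiazepine-site subunits, neuropeptide receptors and astrocyte, oligodendrocyte and oligodendrocyte precursor markers passed towards lower values. Endothelial markers, the immediate early and dissociation-response genes and the ribosomal proteins passed towards higher values. With an estimated correlation each of these 8 had an adjusted p of 0.364 or more. Of the 8, endothelial and oligodendrocyte precursor markers passed camera at the preset correlation with each library left out, and the others did not.

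The third comparison was between age classes, which also differed in depth. Tgtp2, Zfp831 and Oip5 were higher and Jund, Basp1 and Ppp2ca lower in the 18 to 20 week libraries, and these 6 were the genes past the threshold in edgeR (946 had an unadjusted p under 0.05). Ppp2ca, the catalytic subunit of protein phosphatase 2A, had 29.8 ± 11.9 TPM in older against 376.3 ± 96.9 TPM in younger mice (SD, n = 4 each; log2 fold change -3.92 ± 0.48 SE, adjusted p 0.027). Jund, an AP-1 transcription factor, had 7.90 ± 5.65 against 341 ± 199.4 TPM, and Basp1, a growth cone protein, 16.3 ± 17.2 against 417.3 ± 284.9 TPM. Zfp831 and Oip5 had 37.1 ± 18.6 and 125.7 ± 49.3 TPM against 0.0462 ± 0.0498 and 0.556 ± 0.36 TPM. Tgtp2, an interferon-induced GTPase with a near-identical copy whose reads are uncertain, had 0 reads in the younger mice, and in the older mice 348.1 TPM in SST replicate 4 and 23.9 to 90.8 TPM in the other 3 libraries. Leaving out 1 library ended at least 4 of the 6 calls: 2 genes passed without SST replicate 3, and 0 without each of the other 7 libraries. Ionotropic glutamate receptors passed fry towards lower values in older mice (median -2.56, adjusted p = 0.0378, 0 of 12 past the threshold); adjusted p = 0.34 with an estimated correlation in camera. That fry call ended with each of the 8 libraries left out (adjusted p 0.0724 to 0.311). Endothelial markers had a median of 2.32, and 6 of 10 passed adjusted over the list alone (0 to 9 with 1 library left out). Camera gave an adjusted p = 0.34 with an estimated correlation. Other lists also passed camera at its preset correlation. Among them, immediate early and dissociation-response genes were higher in older mice (median 1.55, adjusted p = 8.4e-05). Mural cell and erythrocyte markers were also higher (1.63, 4.1e-06), and ribosomal proteins were lower (-1.19, 3.2e-12). With an estimated correlation each of these lists had an adjusted p of 0.34 or more. The interaction of population and age class had 0 genes past the threshold in edgeR, 467 with an unadjusted p under 0.05, and 76 in DESeq2.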

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

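The count over other splits of the libraries was planned before the data were examined, although how it would be read was set down only after the counts were known; the other tests of explanations here were chosen after the results they bear on had been seen. Of 82 groups of 4 libraries checked for a single distant library, 19 had one (23.2%), where chance gives about 1 in 20. Many of these groups hold near-zero values.

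Sst reached 222.7 TPM in PKCd replicate 2 against 0.209 to 13.7 TPM in the other 3 PKCd libraries. A wrong label is argued against by its Prkcd level, 157.5 TPM, above every SST library. Its microglial sum was also above every SST library. Microglia may contribute to Prkcd, so these values are not independent, and the microglial sum is no marker of the Cre line. An admixture of SST neurons stays open, since members of the fixed SST neuron list went both ways. Tac1 stood at 66.3% of its SST mean in PKCd replicate 2 (75.4 TPM, other PKCd libraries at most 5.20) and Pdyn and Nts at 0.148% (the median of the 3) and 0.061%, while Tac2 (106.9 TPM) and Crh (41.8 TPM) lay above every SST library. A difference between mice or cells also stays open and was not tested.

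Among genes higher in PKCd libraries, Hvcn1 (195.0 TPM against 92.3 to 109.1) and Nckap1l (167.3 against 72.6 to 83.1) stood apart in PKCd replicate 3. In SST libraries single values stood apart for Hvcn1 (2.20 TPM, replicate 3), Havcr2 (0.498, replicate 4) and Il4ra (0.0223, replicate 2). Of the 32 genes, 1 of the 35 splits of the libraries, the real one, gave as many, and the highest other gave 5. This argues against chance but cannot exclude it, since the smallest share that 35 splits allow is 1 of 35. A lower share of neurons that raised all glial markers alike is argued against. The microglial list exceeded the astrocyte and oligodendrocyte lists by 5.90 log2 units or more in PKCd relative to SST libraries, with no overlap. Fewer neurons with more microglia alone would give the same contrast and stays open. Pan-neuronal marker sums in PKCd replicates 3 and 4 (297.4 and 326.3 TPM) lay below every SST library (569.8 to 999.8). Those of PKCd replicates 1 and 2 (1005 and 2379 TPM) lay above. Depth or age class is argued against by medians of 2.90 and 5.61 within the younger and older classes. Exact age differed between the populations within each class, so it cannot be told apart from population there. Microglia or their RNA in the PKCd sorts may account for the microglial markers among these genes. 12 of 12 markers fixed beforehand separated the populations, with C1qb at 9151 and C1qc at 6199 mean TPM in PKCd libraries. None of the 12 is in another fixed list, and all 12 had reads in every SST library. The tdTomato gate is meant to remove unlabelled cells. Oligodendrocyte markers nonetheless summed to at least 12040 TPM in PKCd and 12380 TPM in SST libraries. Carry-over past the gate, reporter activity in microglia and the source of the genes outside the lists were not tested.

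Prkcd was higher in PKCd libraries, and microglia may contribute to it. Its level per 1000 microglial TPM was 2.71 to 6.57 in PKCd libraries and 0 to 60.6 in SST libraries (exact permutation p = 0.829). That p-value cannot decide the question, since the SST mean rests on replicate 4, which had the lowest microglial sum (497.8 TPM). SST replicates 1 and 2 had the highest SST microglial sums (6446 and 1879 TPM). Their ratios of 0.203 and 0 lay below every PKCd library, which speaks against microglia as the main source. SST replicate 3 lay above, at 7.01. The part from neurons and the part from microglia therefore cannot be told apart with 4 libraries each.

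Among GABA-A subunits in PKCd libraries, the distant values were Gabra2 4.95 TPM in replicate 1, Gabra3 8.18 TPM in replicate 2, Gabrg3 2.35 TPM in replicate 3 and Gabra6 0.970 TPM in replicate 4, the last 2 from 2 reads each. In SST libraries Gabrg3 stood apart at 15.8 TPM in replicate 3 (22 reads). Shares of alpha TPM stood apart for Gabra3 (69.2%, PKCd replicate 2) and Gabra6 (66.0%, PKCd replicate 4, and 5.76%, SST replicate 3). Both Gabra6 shares rest on 2 reads, of 3 and 53 alpha subunit reads. Tgtp2 stood apart at 348.1 TPM in SST replicate 4 and Jund at 451 TPM in SST replicate 2. Astrocyte markers summed to 3418 TPM in SST replicate 3. Oligodendrocyte precursor markers summed to 610.8 TPM in PKCd replicate 1 and 2307 TPM in SST replicate 2.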

How the results depend on the processing

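Thinning was chosen after seeing the data. All 32 genes kept their direction in every alternative, which their separation between the populations largely fixed beforehand. The count lay within 1.5 times of 32 with RLE, upper quartile, the 10 CPM filter, limma-voom, the length offset and no age term. It was 269 with no filter (218 higher, 51 lower), 454 with DESeq2, 147 and 68 with limma on log2(TPM + 1) and log2(TPM + 0.1), 61 after thinning, 0 within 8 to 9 weeks, 8 within 18 to 20 weeks, and 10 to 52 with 1 library left out. The older against younger count of 6 was 2 with RLE, 249 with no filter, 2 with the 10 CPM filter, 568 with DESeq2, 0 with limma-voom, 53 and 12 with the limma fits on TPM, and 0 to 2 with 1 library left out; 2 of 35 splits gave as many, so by that count chance is not excluded, but the second is the population split itself (26) and the other 33 gave 0. The interaction count of 0 was 25 with no filter and 76 with DESeq2. Of the lists, 13 passed camera and 0 with an estimated correlation (microglial median 4.30, adjusted p = 0.14), and 6 to 12 with 1 library left out; 1 of 35 splits gave as many, the highest other giving 9. Gabra4 turned positive with limma-voom (0.997), the replicate block (1.23) and without SST replicate 1 or 4 (0.338 and 0.0336, in a range of -2.79 to 0.338 with 1 library left out), and Gabra3 within 8 to 9 weeks (0.389). The ribosomal list median was -0.0555 without SST replicate 2 and 0.362 without SST replicate 4, its range with 1 library left out. Share differences, in percentage points, changed sign with 1 library left out for Gabra4 (-8.12 to 24.4, negative without PKCd replicate 3), Gabra5 (-9.83 to 0.396, positive without SST replicate 1) and Gabra3 (-24.6 to 10.2, positive without SST replicate 3). The cause was not tested for these changes. With the replicate number as a block 24 genes passed; same-numbered libraries had deviations correlated at 0.0764, 0.124, 0.0615 and 0.174, and not every library correlated best with its own number, so the numbers were not taken to pair mice. Alpha shares and marker sums had 0 past the adjusted threshold in every alternative, where sign-flip and left-out tests cannot go below 0.125 and 0.0571. The age class median over all genes shifted by 0.104 with RLE and by 0.285 and 0.27 with the limma fits on TPM. Low depth limits low genes in the 18 to 20 week libraries.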

Other observations

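4 further genes of the 32 higher in PKCd libraries were chosen after their values were seen. Ctsd, the protease cathepsin D, had 6310 ± 1786 TPM in PKCd and 549.5 ± 337.5 TPM in SST libraries (SD, n = 4 each). Hexa, a lysosomal hexosaminidase subunit, had 619.4 ± 121.2 against 115.1 ± 43.9 TPM, and Lgmn, the protease legumain, 2413 ± 1134 against 287.9 ± 43 TPM. Fermt3, an integrin activator of blood cells, had the smallest adjusted p in edgeR (0.00406), at 152 ± 38.1 against 1.25 ± 0.357 TPM.

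Of 8 border macrophage markers, a list added after the data were seen, 4 could be tested, with a median log2 fold change of 3.78; 0 passed over all genes and 1 adjusted over the list alone. The list had an adjusted p of 0.0655 in fry and 0.0343 in camera; adjusted p = 0.314 with an estimated correlation. The summed TPM of its members overlapped, at 39.6 to 513.6 in PKCd and 5.13 to 181.5 in SST libraries (exact permutation p = 0.2). None of 8 monocyte, neutrophil and lymphocyte markers had enough reads to be tested, and they summed to 5.35 ± 6.43 TPM in PKCd and 67.3 ± 91.9 TPM in SST libraries (SD, n = 4 each). Of 12 pan-neuronal markers, 11 were tested with a median of 0.23 and 0 past the threshold. They summed to 1005, 2379, 297.4 and 326.3 TPM in PKCd replicates 1 to 4 and to 569.8 to 999.8 TPM in SST libraries (exact permutation p = 0.714), so the highest sum was that of PKCd replicate 2, the PKCd library with high Sst. The neuropeptide precursor Nts had 402.8, 64.9, 235 and 196.2 TPM in SST replicates 1 to 4 and 0, 0.137, 130.5 and 74.9 TPM in PKCd replicates 1 to 4.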
